A study of Escherichia coli and Escherichia coli
Staphylococcus aureus and Staphylococcus aureus with 18 samples.

How the data were processed

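The samples were 8 PETRI-seq libraries of fixed cells and 10 bulk RNA-seq libraries. Exponential cells had grown for 2 h and stationary cells for 5 h after dilution, per the labels. The deposited PETRI-seq files hold UMI counts with barcodes in rows and operon features in columns, made by the authors before deposition and not normalized. Every value was checked to be a whole number of at least 0. The submitters' processing notes name cutadapt 1.18, UMI-tools 0.5.5, BWA 0.7.17 and featureCounts 1.6.3 for these files. Each file name gives a read threshold that differs between libraries and whose meaning is not stated. The deposited bulk files hold raw read counts per operon feature from featureCounts 1.6.3 with strand setting 1, per the file headers, and were not normalized. The headers do not name the aligner. Both kinds of file use operon features of E. coli U00096 and of S. aureus CP000255 with its plasmids, with pooled ribosomal RNA and with antisense features, which the files of 1.06 and 1.10 do not list. Coordinates are those of the file headers, counted from 1. The E. coli and the mixed annotation of the wild-type bulk table differ, since operons of the same name in both species are summed there.

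Of the bulk columns, 5 could be matched to a sample by the code in the sample's description. The other 5 could be matched to a group only, namely 3 columns of differently preserved exponential cells and 2 columns of exponential and stationary wild-type cells, because the labels name the table and not the column. The wild-type columns were therefore left out of all tests and are given as values in the closing section. No column of values per sample was left out otherwise. The growth stage field of 2.01no_det says exponential, while its description gives both stages by plate column, and the description was used.

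A barcode entered the analysis with at least 20 UMIs outside ribosomal RNA on sense features. In species mixtures it was E. coli or S. aureus with at least 90% of UMIs from that species and otherwise mixed. Depths, sums, clusters and prophage counts of a species used barcodes with at least 20 UMIs from that species itself, so their numbers are lower than those in the mixing. Growth stage came from the reverse transcription well in 2.01 and 2.01no_det (columns 1 to 6 exponential, columns 7 to 12 stationary). Reporter tags GFP and RFP in 1.06, 1.10 and 1.12 were taken from the authors' barcode names and were not called anew from reporter counts. The labels of 1.12 say that GFP cells were exponential and RFP cells stationary. Library 1.12det was planned for the stage test, but its file holds exponential barcodes and no stationary ones, so the test had 2 libraries and not 3. Antisense features and ribosomal RNA were left out of all tests, except in alternatives that kept them. Choices of tests, lists, markers and named genes were made before the data were examined, except where the text says otherwise.

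For the PETRI-seq stage test, UMIs were summed over barcodes per library and stage, since cells are not replicates. The sums held 847927 UMIs (3512 barcodes) and 142871 UMIs (3762) in 2.01, and 93718 UMIs (582) and 20214 UMIs (649) in 2.01no_det, exponential before stationary. The sums were fitted with edgeR 4.0.16 quasi-likelihood tests after filterByExpr and TMM scaling, with library as a block because each library holds both stages. TMM factors ran from 0.684 to 1.32. The fit had 1 residual degree of freedom, a common dispersion of 0.0147 and a prior that pooled the spread fully over features. The bulk stage test used the same tool on 2 fixed exponential libraries and 1 fixed stationary library of reporter cells, with a common dispersion of 0.0413 and prior degrees of freedom of 7.61. Values are called with a Benjamini-Hochberg adjusted p under 0.05, and tests are 2-sided. Standard errors are the absolute log2 fold change over the square root of the F statistic. CPM values of named features are TMM-scaled. Nothing in the labels says that libraries came from separate cultures, so p-values measure mainly technical spread.

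Precision was tested on simulated data with 200 changed features, at the depth and size of each comparison. For PETRI-seq, with 1183 features, edgeR recovered 47% of 2-fold and 92% of 4-fold changes with 8 false calls among 147, and DESeq2 12% and 52% with 0 false calls among 64. For bulk, with 2468 features, edgeR recovered 30% and 80% with 5 false calls among 115, and DESeq2 15% and 68% with 0 among 83. Simulated changes went up or down at random, with the same dispersion for every feature and no library effect. The real tests called 848 PETRI-seq and 1320 bulk features, and their fold changes shifted with the scaling. The simulated rates therefore need not hold for the real tests.

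The 22 E. coli and 6 S. aureus gene lists hold a feature when the feature is the gene or an operon whose name holds the gene. The E. coli lists were ribosomal proteins, translation factors, ATP synthase, RpoS and general stress, ribosome hibernation, acid resistance, motility, TCA cycle, glyoxylate and acetate use, glycolysis, purine and pyrimidine synthesis, outer membrane proteins, heat shock, cold shock, SOS response, phosphate starvation, amino acid breakdown, anaerobic and fermentation, sugar uptake, iron uptake, cell division, and small and stable RNAs. The S. aureus lists were ribosomal proteins, virulence factors, agr and phenol-soluble modulins, heat shock, and the prophages phiSA2 and phiSA3. Lists were tested with limma 3.58.1 camera at a preset correlation of 0.01, and checked with an estimated correlation and with fry. Both fits left 1 residual degree of freedom, on which the estimated correlation and its test rest. Hardly any list could pass that check, so it cannot decide whether a list moved. Lists overlap, as RpoS, acid resistance and ribosome hibernation share features. Ribosomal proteins, translation factors and cold shock share features too, such as metY-rimP-nusA-infB-rbfA-truB-rpsO-pnp, so their changes are not fully separate evidence.

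Named features of a tested comparison were the 12 with the largest rise and the 12 with the largest fall among those called, with an average log2 CPM of at least 6 and the same direction in every library, plus up to 4 members of each list by smallest p and any member of the RpoS, hibernation and outer membrane lists. For 1 library against 1 they were among the 10 features with the largest and the 10 with the smallest log2 ratio. The features metBL and btsT in the comparison of the assays, cysPUWAM among those higher than in bulk and the genes of single wells follow from their ranks or from tests chosen after their values were seen. A fold against 0 counts is a bound with a floor of 3 counts over the group, and ratios with 1 to 3 counts carry an exact binomial counting interval. Gene copies such as the insH family, tufA and tufB, and ribosomal RNA share reads, so their single values are uncertain.

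Ratios of 1 library against 1 used a prior count of 5, which brings ratios of low counts nearer to 1, and features with at least 100 reads in either library, or 50 UMIs for PETRI-seq sums. A list median was ranked among 10000 random lists of the same size and like mean expression. Correlations used log2 of CPM plus 1. Shares carry exact (Clopper-Pearson) 95% intervals, shares of 0 also the limit that a floor of 3 counts gives, and medians 95% intervals by rank. PCR reads of bulk libraries are not independent molecules, so intervals and floors cover counting error only.

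Clusters were made per library with scikit-learn 1.9.0, igraph 0.11.9 and leidenalg 0.10.2. Log-normalised counts of the 1000 most variable features gave 10 principal components. A graph of nearest neighbours, weighted by shared neighbours, entered Leiden clustering at resolution 0.5 with seed 0. A cluster was named by its share of fixed exponential or stationary markers relative to the other clusters of its library. A name needed at least a 2-fold difference in the stationary marker share and at least 3 markers detected, with further limits on leading features and depth. On simulated barcodes this separated profiles of both stages fully, and barcodes of a single profile with unequal depths were partly sorted by depth. Prophage barcodes needed at least 5 UMIs from a prophage, and the number for an even spread came from a Poisson model with each barcode's depth.

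Alternatives tried were DESeq2 1.42.0, library totals in place of TMM, no filter, no block, UMI minimums of 10 and 40, sums thinned to the smallest, ribosomal RNA kept, purities of 80% and 95%, pseudocounts of 0.1 and 10 CPM, k-means with 2 clusters, and leaving out each library. Added after the data were seen were 1.12 by reporter tag, antisense features kept, ribosomal RNA counted in the mixing, the detergent classes of 1.12det and clusters of thinned barcodes. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 and R 4.3.3 were used.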

Results

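PETRI-seq labels the RNA of fixed bacterial cells with 3 successive well barcodes, the first added by reverse transcription and the others by ligation, so that a barcode combination stands for a cell. The data held 18 samples, 8 PETRI-seq libraries and 10 bulk RNA-seq libraries. Cells were Escherichia coli in exponential growth (2 h) or stationary phase (5 h) and exponential Staphylococcus aureus, counted on the annotation of strain USA300. Libraries 1.06SaEc, its replicate, 2.01 and 2.01no_det mixed both species. Libraries 1.06, 1.10, 1.12 and 1.12det held E. coli alone, and in 1.06, 1.10 and 1.12 the authors' barcode names gave part of the barcodes a GFP or RFP reporter tag. The PETRI-seq libraries held between 706848 (1.12) and 9527355 (2.01) UMIs, of which sense ribosomal RNA took between 70.1% (1.06SaEc replicate) and 89.2% (1.06). These totals include antisense features, ribosomal RNA among them, except in 1.06 and 1.10, whose files list none. The shares of 1.06 and 1.10 are therefore not on a like basis with the others. Bulk libraries held between 620755 and 7925181 counted reads. Unless a test is named, a comparison had 1 library per condition and no replicates, and intervals cover counting error only.

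In 2.01 and 2.01no_det, exponential E. coli carried several times more messenger RNA UMIs per barcode than stationary E. coli or S. aureus, while the gaps in 1.06SaEc and between the tags of 1.10 were smaller. Among barcodes with at least 20 UMIs of their own species outside ribosomal RNA, exponential E. coli of 2.01 had a median of 229 UMIs (quartiles 142 and 325, n = 3512 barcodes) from 104 features. Stationary E. coli of the same library had a median of 34 UMIs (quartiles 26 and 44, n = 3762) from 30 features, and S. aureus had 51 UMIs (n = 1219). In 2.01no_det these medians were 153.5 (n = 582), 28 (n = 649) and 35 UMIs (n = 201). In 1.06SaEc the exponential E. coli median was 50 UMIs (quartiles 32 and 79, n = 639) and the S. aureus median 27 (n = 4255). In 1.10 the medians were 76 UMIs for GFP-tagged barcodes (n = 2083), 46 for RFP-tagged barcodes (n = 599) and 34 for untagged barcodes (n = 3635). The minimum of 20 UMIs shaped these medians where depth was low, since in 1.06SaEc the S. aureus median was 18 with a minimum of 10 UMIs and 47 with a minimum of 40.

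**Figure D1:**
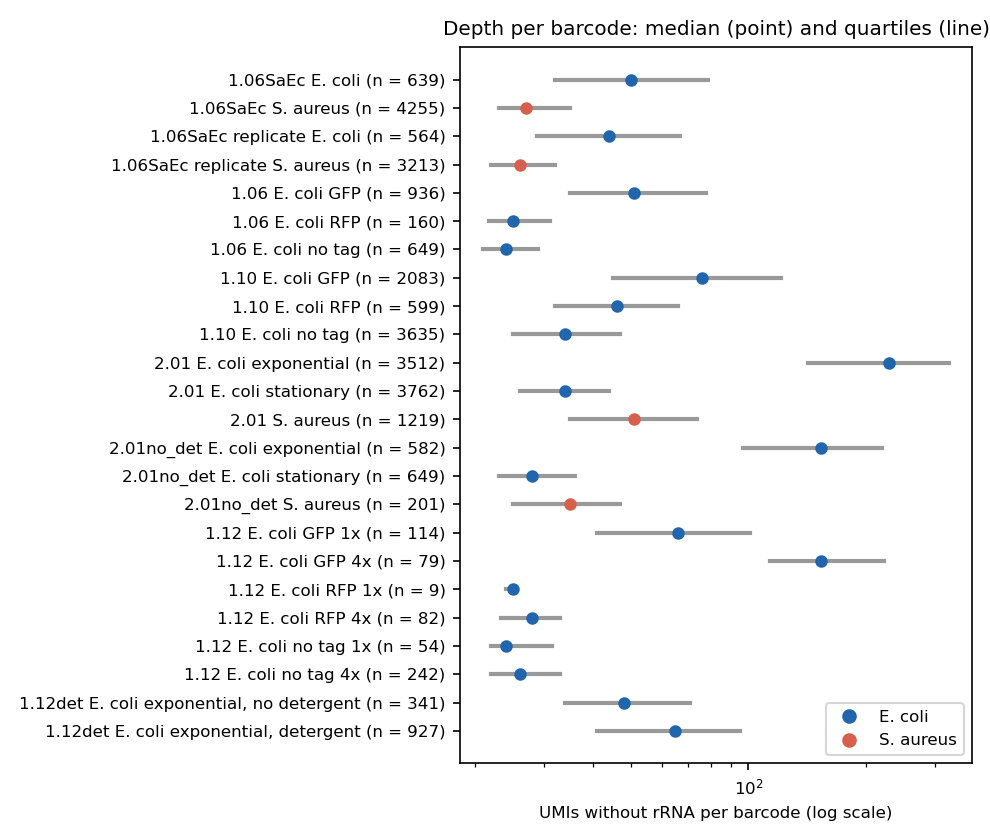
Depth per barcode in each library, species and labelled class, as UMIs outside ribosomal RNA on a log scale. Points are medians and lines run between the quartiles; exponential E. coli of 2.01 lies highest at 229 UMIs.

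Species mixtures ask how often a barcode combination holds RNA of both species. Barcodes with more than 1 cell of the same species do not show as mixed, so the mixed share does not count them. In 1.06SaEc, 22 of 4950 barcodes (0.444%, exact binomial 95% interval 0.279 to 0.672%) had less than 90% of UMIs from either species, beside 642 E. coli and 4286 S. aureus barcodes. The replicate library had 12 mixed barcodes of 3823 (0.314%, 0.162 to 0.548%). Library 2.01 had 309 mixed barcodes of 8911 (3.47%, 3.10 to 3.87%), and these lay mainly on the plate columns that held stationary cells. Columns 1 to 6, with exponential E. coli, had 18 of 4156 (0.433%), and columns 7 to 12, with stationary E. coli, had 291 of 4755 (6.12%, 5.46 to 6.84%). Library 2.01no_det had 17 mixed barcodes of 1473 (1.15%, 0.674 to 1.84%), all on columns 7 to 12, while 0 of 679 barcodes on columns 1 to 6 were mixed, which allows a share of up to 0.442% by a floor of 3 counts and 0.542% by the exact interval. Of the mixed barcodes on columns 7 to 12 of 2.01, 251 held mostly E. coli RNA, and 3 of these (0.247 to 3.45%) held at least 122.2 S. aureus ribosomal RNA UMIs, the 5th percentile of pure S. aureus barcodes. All 291 had medians of 26 E. coli, 4 S. aureus and 3 S. aureus ribosomal RNA UMIs. Pure barcodes of these columns had medians of 3 (E. coli) and 308 (S. aureus) S. aureus ribosomal RNA UMIs. On these columns of 2.01no_det this median was 4 (quartiles 2 and 113) in the 17 mixed and 225 in pure S. aureus barcodes. In 2.01 the values argue against a whole S. aureus cell in most of the 251. The share of mixed barcodes moved with the UMI minimum and the purity, to 17.3% in 2.01 with a purity of 95% and 0.640% with ribosomal RNA counted.

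**Figure D2:**
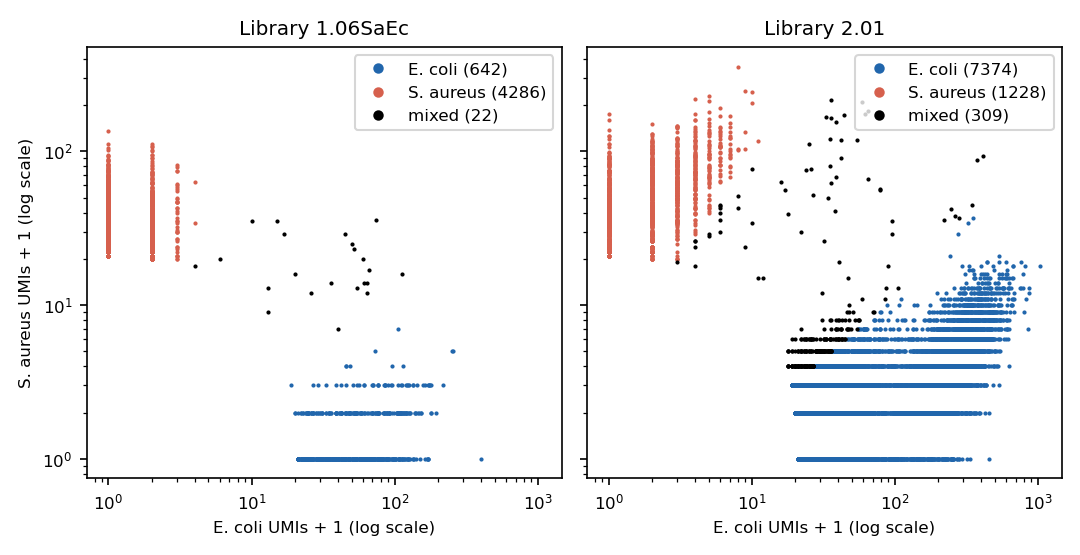
E. coli against S. aureus UMIs outside ribosomal RNA per barcode, each plus 1 on log scales, for 1.06SaEc and 2.01. Each point is a barcode with at least 20 UMIs; 22 barcodes of 1.06SaEc and 309 of 2.01, in black, are mixed.

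The central biological comparison set stationary against exponential E. coli, with the growth stage of each barcode known from its reverse transcription well. Stage went fully with the plate columns, which were the same in 2.01 and 2.01no_det. Within these libraries an effect of stage therefore cannot be told apart from an effect of the wells and their oligos. UMIs of features found concentrated in single wells of 2.01 made up 0.184% of its E. coli UMIs. On a scale relative to the typical feature, stationary cells of 2.01 and 2.01no_det differed in several groups. They held far more RNA of the general stress regulon under the sigma factor RpoS, of acid resistance and of phosphate starvation. They held far less RNA for ribosomal proteins and purine synthesis. The DNA-protecting protein gene dps (U00096, 848408 to 848911) rose from 49.0 ± 4.06 to 10188 ± 331 CPM (mean ± SD, n = 2 sums per stage), a log2 fold change of 7.72 (SE 0.30, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 3.1e-114). The operon wrbA-yccJ (1066864 to 1067708) rose by a log2 fold change of 10.37 (SE 0.38), from 4 to 1831 UMIs. The glutamate decarboxylase and antiporter operon gadBC (1568954 to 1572045) rose by 9.71 (SE 0.35), and the periplasmic acid chaperones hdeAB-yhiD by 8.15 (SE 0.31). The ribosomal protein operon rpsJ-rplCDWB-rpsS-rplV-rpsC-rplP-rpmC-rpsQ (3448314 to 3453270) fell from 117918 ± 16689 to 516 ± 67.7 CPM, a log2 fold change of -7.84 (SE 0.35, edgeR adjusted p = 1.3e-90). Of 1183 features tested, 421 rose and 427 fell in stationary phase. With library totals in place of TMM scaling, which raised the median log2 fold change of all features by 0.89, 651 rose and 313 fell, so all changes are relative to the typical feature. Stationary barcodes of 2.01 also held fewer UMIs (median 34 against 229), so a rise on this scale need not be a rise per barcode.

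Other large rises were phoA-psiF, alkaline phosphatase (log2 fold change 8.50, SE 0.33), yeaGH (8.20), hdeD (8.18) and the acid-induced glutaminase operon glsA-ybaT (8.03). The peroxiredoxin gene osmC had 0 UMIs in exponential and 145 in stationary cells, at least 151-fold higher with a floor of 3 counts over the group. Few exponential UMIs made some ratios imprecise. The paralogous ribosomal protein operon ykgMO had 1 exponential and 607 stationary UMIs (ratio 1901, counting interval 340 to 75192), yahO had 1 and 142 (ratio 445, 78.5 to 17684) and uspF had 2 and 155 (ratio 243, 66.1 to 2022). Among the falls, the nucleoside diphosphate kinase gene ndk had 557 exponential and 0 stationary UMIs, at least 59.3-fold lower. With the same floor, yncD was at least 19.7-fold lower, yeiP at least 15.3-fold and the tRNA operon lysT-valT-lysW at least 13.4-fold. The xanthine transporter gene xanP fell from 940 UMIs to 1 (ratio 300.2, 53.8 to 11870), rpsT from 761 to 1 (243, 43.5 to 9612), plaP from 745 to 2 (119, 32.8 to 984) and the superoxide dismutase gene sodA from 1063 to 3 (113, 38.6 to 550). The porin gene ompF fell by 7.14 on the log2 scale (SE 0.36), rplM-rpsI by 7.32 and rpmH-rnpA by 6.76. Of the 848 features called, 839 had the same direction in both libraries, on which the calls themselves rest. The test had 2 sums per stage, the labels do not say whether the libraries came from separate cultures, and the p-values therefore measure mainly technical spread. Counts of calls fell to 557 with DESeq2, to 318 with sums thinned to the smallest and to 528 with 1.12 added, and yncD, yeiP and lysT-valT-lysW did not pass by DESeq2.

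Gene lists fixed in advance showed the groups that moved together. All 20 measured ribosomal protein features fell (median log2 fold change -4.85), among them rpsF-priB-rpsR-rplI (-6.54), as did all 12 translation factor features, among them rpsLG-fusA-tufA (-4.28, SE 0.27) and tff-rpsB-tsf (-3.97, SE 0.24). Both named translation factor operons also hold ribosomal protein genes and count in both lists. The camera test gave adjusted p = 6.6e-13 for ribosomal proteins and 4.2e-06 for translation factors (edgeR fit, Benjamini-Hochberg over the lists), and adjusted p = 0.827 for both with an estimated correlation. The estimated correlation rests on 1 residual degree of freedom, here and for the lists below, so it cannot decide. The ATP synthase operon atpIBEFHAGDC, a list of 1 feature, fell by 3.54 (SE 0.24). All 30 RpoS features rose (median 6.03), among them osmY (5.92, SE 0.38), the catalase gene katE (3.20, SE 0.49) and, least of those named, ecnAB (1.47, SE 0.41, edgeR adjusted p = 0.00065). All 7 acid resistance features rose too (median 7.49). Camera gave adjusted p = 4.3e-13 and 4.2e-05 for these lists, and adjusted p = 0.827 for both with an estimated correlation. Of 7 ribosome hibernation features 6 rose (median 5.03), including raiA (3.50, SE 0.37), bdm-sra (5.03, SE 0.62) and the hibernation factor gene rmf, with 2 exponential and 102 stationary UMIs (ratio 160, 43.1 to 1336), and the long operon holding hpf did not pass (-0.05). Camera gave adjusted p = 0.0062, and adjusted p = 0.827 with an estimated correlation. With library totals 11 of 12 translation factor features fell and 7 of 7 hibernation features rose.

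Purine and pyrimidine synthesis fell in 17 of 18 features (median -3.50, camera adjusted p = 2.3e-05, adjusted p = 0.853 with an estimated correlation) and in 14 with library totals, among them guaBA (-6.06, SE 0.29), purL (-4.45) and purHD (-4.79). All 4 cold shock features fell (median -3.80, camera adjusted p = 0.0030, adjusted p = 0.827 with an estimated correlation), including the cold shock protein gene cspA (-4.76, SE 0.26). All 4 phosphate starvation features rose (median 5.58, camera adjusted p = 0.0030, adjusted p = 0.827 with an estimated correlation), including the phosphate transporter pstSCAB-phoU (6.27, SE 0.26). All 9 anaerobic and fermentation features rose (median 2.92, camera adjusted p = 0.00019, adjusted p = 0.827 with an estimated correlation), including hydrogenase 1, hyaABCDEF (5.28, SE 0.26), and fumarate reductase, frdABCD (2.92, SE 0.25). All 5 small and stable RNA features rose (median 1.85, camera adjusted p = 0.031, adjusted p = 0.827 with an estimated correlation), including csrB (4.93, SE 0.30), which binds the regulator CsrA, and the ribosome rescue RNA ssrA (1.85, SE 0.20).

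The remaining 11 lists gave camera adjusted p of at least 0.333, and members moved both ways in all but glyoxylate and acetate use. TCA cycle features split into 3 up, including acnA (3.28, SE 0.30), and 3 down of 8, including sdhCDAB-sucABCD (-2.74, SE 0.22), with a median of -0.24 that became 0.59 with library totals. Outer membrane proteins split into 3 up and 6 down of 11 (median -1.33), with ompW (4.23) and ompC (0.94, SE 0.20) higher. Iron uptake split into 3 up, including bfd-bfr (7.12, SE 0.41), and 4 down of 9, including fhuACDB (-3.72), with a median of -0.91 that became 0.01 with library totals. Glycolysis had 4 up, including pfkA (2.47), and 2 down of 11 (median 0.32), against 10 up and 0 down with library totals. Amino acid breakdown had 5 up, including csiD-lhgO-gabDTP (4.03), and 1 down, sdaCB (-5.35), of 8 (median 1.12). Heat shock had 2 up, including clpB (3.37), and 1 down of 8 (median 0.08, and -0.14 by DESeq2), against 5 up and 0 down with library totals (median 0.94). Glyoxylate and acetate use had 1 up, aceBAK (1.83), of 2 (median 0.68). Sugar uptake had 2 up, including manXYZ (1.07), and 3 down of 10, including rbsDACBKR (-2.17), with a median of -0.30 that became 0.61 with library totals. Cell division had 1 up and 1 down, mreBCD (-3.26), of 4, with a median of -0.49 that became 0.36. Motility had 1 up, fliAZ-tcyJ (SE 0.33, from 64 to 243 UMIs), and 1 down of 5, with a median of -0.15, a mean of 0.31, camera upward and a median of 0.77 with library totals. The SOS response had 1 up, uvrB (1.10), and 1 down, lexA-dinF (-1.52), of 7, with a median of 0.17, a mean of -0.04 and camera downward, against 5 up and 0 down with library totals (median 1.02). The other counts up and down with library totals were 5 and 3 for the TCA cycle, 5 and 5 for outer membrane proteins, 3 and 3 for iron uptake, 6 and 1 for amino acid breakdown, 1 and 0 for glyoxylate use, 4 and 2 for sugar uptake, and 2 and 1 for both cell division and motility. Adjusted over the list alone, the counts equalled those over all features except for sugar uptake, with 2 up and 2 down. By DESeq2 ecnAB, ompC, manXYZ and uvrB did not pass, nor did ompC with 1.12 added or lexA-dinF with library totals. The fry test, which asks whether a list moves one way on balance, gave adjusted p of at least 0.238 for all lists. It rests on the same 1 residual degree of freedom, so its lack of calls cannot show that a list did not move.

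Bulk RNA-seq of fixed reporter cells asked the same growth stage question, with 2 exponential libraries and 1 stationary library. Relative to the typical feature, stationary cells held more RNA of metE, zinT and the cysDNC operon, of the RpoS regulon and of anaerobic metabolism. They held less of asnA, ribosomal proteins, translation factors and heat shock genes. The methionine synthase gene metE (4013053 to 4015314) rose from 15.7 ± 0.673 CPM (SD, n = 2) to 41659 CPM (n = 1), a log2 fold change of 11.37 (SE 0.28, edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 8.5e-08). The zinc-binding protein gene zinT rose by 9.15 (SE 0.24), the sulfate activation operon cysDNC by 8.62, sulfite reduction cysJIH by 7.64 and the sulfate-binding protein gene sbp by 6.67. Other large rises were wrbA-yccJ at 8.71, yahO at 7.82, ykgMO at 7.68, ycaC (from 1.51 to 226 CPM), fbaB at 7.10, hdeAB-yhiD at 6.74 and ycgB at 6.72. The asparagine synthetase gene asnA fell from 202 ± 99.8 to 3.56 CPM (-5.82, SE 0.56, edgeR adjusted p = 4.0e-05). The next falls were suhB (-5.42), plaP (-5.14), ndk (-4.98), ydiY (-4.59), gpt (-4.45), tyrTV-tpr (-4.24), cspF (-4.20), btsT (-4.16), rlmG (-4.10), rpmH-rnpA (-4.06) and fadL (-3.98). Of 2468 features 668 rose and 652 fell. With library totals, which raised the median of all features by 0.37, 850 rose and 494 fell. A single stationary library leaves the spread to the exponential pair and so assumes that stationary libraries vary as much. The stationary library held RFP cells (0 GFP and 9633 RFP reads) and the exponential pair a GFP culture and a mix of GFP and RFP cultures, so reporter went in part with growth stage.

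In the bulk libraries 30 of 31 RpoS features rose and 0 fell (median 4.57), including dps (6.45, SE 0.25) and katE (5.83, SE 0.29). Ribosome hibernation rose in 6 of 7 (median 5.20), including rmf (5.20) and raiA (3.75), and acid resistance in 7 of 10 (median 3.77), including gadAXW (4.75). Camera adjusted p was 6.4e-29, 2.1e-07 and 6.0e-07 for these lists, and adjusted p = 0.654 for all 3 with an estimated correlation. All 20 ribosomal protein features fell (median -1.64, camera adjusted p = 1.5e-08), as did all 12 translation factor features (median -1.64, camera adjusted p = 6.6e-05), including efp (-2.53), with adjusted p = 0.656 for both with an estimated correlation. Anaerobic and fermentation features rose in 8 of 9 (median 3.62, camera adjusted p = 2.3e-06, adjusted p = 0.654 with an estimated correlation), including adhE (3.72) and frdABCD (4.05). Heat shock fell in 7 of 9 (median -2.08, camera adjusted p = 0.00070), including dnaK-tpke11-dnaJ (-2.55), and cold shock in 5 of 6 (median -1.80, camera adjusted p = 0.038), with adjusted p = 0.656 for both with an estimated correlation. The SOS response rose in 8 of 12 (median 1.23, camera adjusted p = 0.045, adjusted p = 0.656 with an estimated correlation), including sulA (2.92) and recN (2.35). Purine and pyrimidine synthesis had 4 up and 11 down of 18 (median -0.96, camera adjusted p = 0.039, adjusted p = 0.656 with an estimated correlation), including rph-pyrE (-3.98) and guaBA (-2.60). With library totals the counts up and down were 0 and 11 for translation factors, 8 and 0 for acid resistance, 1 and 7 for heat shock, 9 and 0 for the SOS response and 5 and 8 for purine and pyrimidine synthesis.

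The other bulk lists gave camera adjusted p of at least 0.118. Members up and down were 5 and 0 of 8 for the TCA cycle (median 0.72), 2 and 0 of 2 for glyoxylate use (2.02), 6 and 0 of 11 for glycolysis (0.78) and 3 and 0 of 5 for phosphate starvation (1.36). They were 5 and 2 of 9 for amino acid breakdown (2.08), 5 and 3 of 14 for sugar uptake (0.11), 3 and 2 of 13 for motility (0.45) and 1 and 3 of 5 for cell division (-0.94). Small and stable RNAs had 2 up, including csrB (5.50, SE 0.22), and 2 down of 9, with a median of -0.31 that became 0.05 with library totals, a mean of 0.05 and camera upward. Iron uptake had 3 up and 3 down of 11, with a median of -0.97, a mean of -0.45 and camera upward. Outer membrane proteins had 1 up, ompC (1.00, SE 0.22, edgeR adjusted p = 0.0047), and 2 down of 11, with a median of 0.21, a mean of 0.10 and camera downward, against 6 up and 2 down with library totals (median 0.58). The other counts up and down with library totals were 6 and 0 for the TCA cycle, 8 and 0 for glycolysis, 6 and 1 for amino acid breakdown, 5 and 1 for sugar uptake, 4 and 1 for motility, 1 and 2 for cell division, 3 and 1 for both small and stable RNAs and iron uptake, and as above for glyoxylate use and phosphate starvation. The gene ompF did not pass in bulk (-0.33, SE 0.27, edgeR adjusted p = 0.33) and had the opposite sign with library totals (0.05). The ATP synthase operon was 1 feature. Adjusted over the list alone, the counts up and down were 2 and 1 for motility, 5 and 11 for purine and pyrimidine synthesis, 0 and 8 for heat shock, 6 and 2 for amino acid breakdown and 3 and 4 for iron uptake, and for other lists they equalled those over all features.

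**Figure D3:**
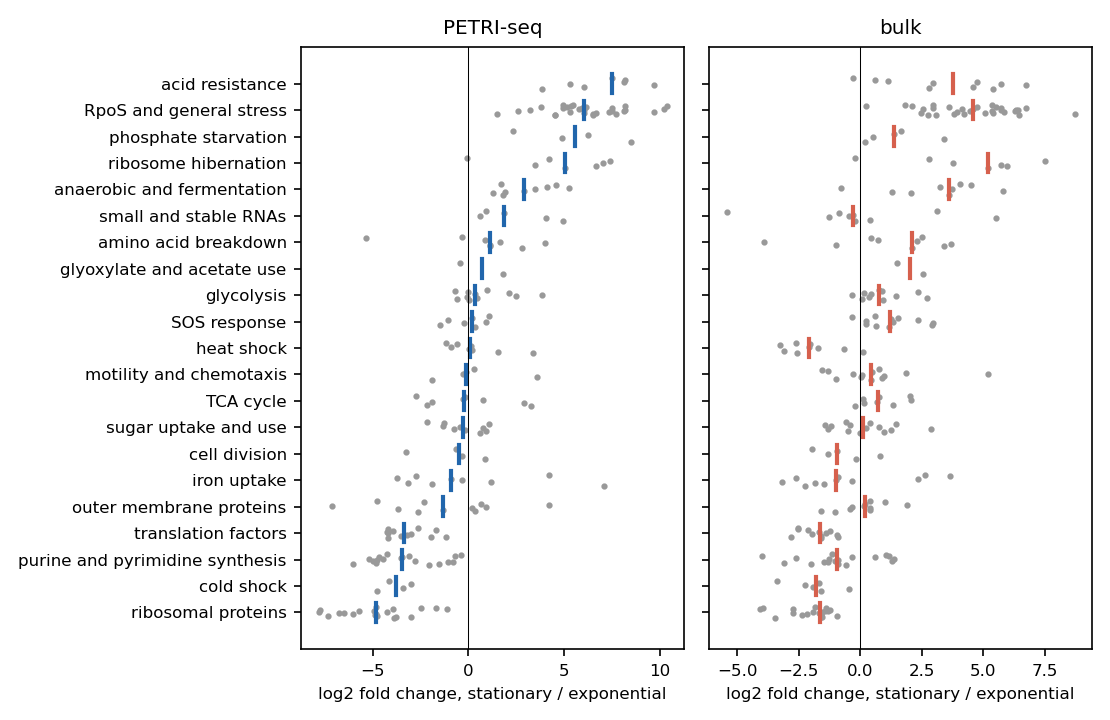
Log2 fold change, stationary over exponential, of each measured feature of the E. coli gene lists in PETRI-seq and in bulk. Gray points are features, whose fitted values depend on the prior count where a stage has 3 counts or fewer, and vertical lines are list medians; RpoS medians lie at 6.03 and 4.57 and ribosomal protein medians at -4.85 and -1.64.

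Summed single cells and bulk cultures gave related growth stage changes. Across 1182 features tested in both, log2 fold changes had a Pearson correlation of 0.841 (0.823 to 0.857) and a Spearman correlation of 0.869, features not being independent replicates. The sign was shared by 86.2%. Features that rose in both numbered 330, against 147 if calls were independent, and 349 fell in both, against 147. The slope of PETRI-seq on bulk was 1.13. A further 13 features changed in opposite directions, including purHD (-4.79 in PETRI-seq, 1.16 in bulk), the pyruvate transporter gene btsT (1.74 and -4.16) and metBL (-1.48 and 4.20). The PETRI-seq cells were wild type and the bulk cells carried reporters, and the difference between the assays was not tested.

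**Figure D4:**
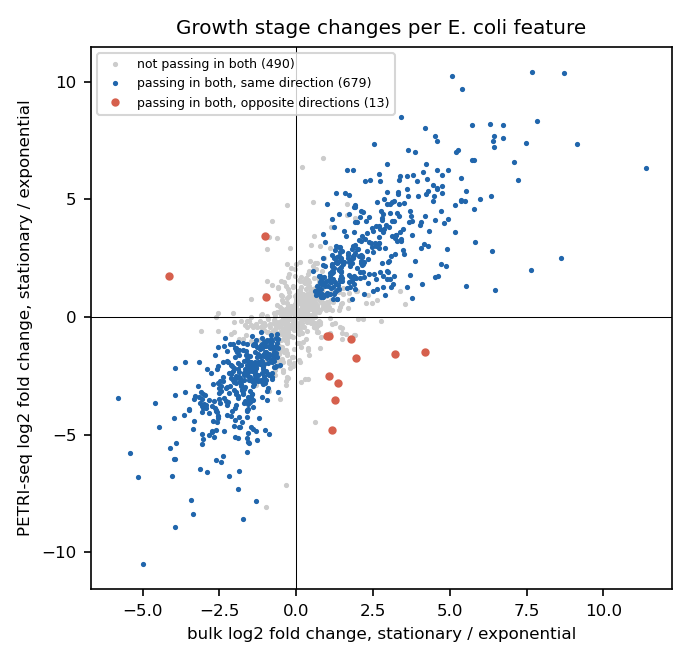
Log2 fold change, stationary over exponential, per E. coli feature in bulk (horizontal) and PETRI-seq (vertical). Points are features tested in both; 679 passed in both in the same direction and 13 in opposite directions. Fitted values depend on the prior count where a stage has 3 counts or fewer.

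Replicate libraries and bulk RNA show how well sums over cells measured expression. In 1.06SaEc and its replicate, log2 CPM of summed barcodes had a Pearson correlation across features of 0.502 (0.466 to 0.536) for E. coli, with 1801 features and a Spearman correlation of 0.728. For S. aureus it was 0.850 (0.834 to 0.864), with 1338 features and a Spearman correlation of 0.931. Features with at least 10 counts in both gave 0.970 (302 features) and 0.980 (581). The variance between the libraries was 1.12 times that of counting error in E. coli (chi-square per degree of freedom, chi-square test p = 0.023). In S. aureus it was 1.21 times (chi-square test p = 1.8e-05). Against fixed bulk RNA, the sums of 1.06SaEc had a Pearson correlation of 0.817 for E. coli (2547 features) and 0.913 for S. aureus (1504), and those of its replicate 0.804 and 0.897. With both libraries summed, small and stable RNAs were far lower in PETRI-seq, with a median log2 ratio of -3.73 (1 of 7 higher, percentile 0.00 among random lists of like expression). The regulatory RNA csrC had 0 UMIs against 1016 bulk reads, and 9 copies of the insertion sequence gene insH had 0 UMIs against 557 to 662 reads each. TCA cycle features were higher in PETRI-seq as a group (median log2 ratio 0.87, 6 of 8 higher, percentile 99.7), as were cysPUWAM (2.84), yejO (2.94) and dinG-ybiB (2.54). Ribosomal proteins had a median of -0.25 in E. coli (percentile 4.17) and -0.10 in S. aureus (percentile 60.7). The median of all S. aureus features was -0.28. In S. aureus virulence factors had -0.62 (2 of 15 higher, percentile 10.1), heat shock -0.39 (1 of 5, percentile 26.5), phiSA2 0.24 (6 of 10, percentile 93.5) and phiSA3 0.08 (9 of 16, percentile 89.2). The agr list held 2 features, too few for a median, agrB-agrD (0.45) and agrC-agrA (-0.20). In S. aureus the lysine permease gene lysP (2.75) and a phiSA3 prophage operon that starts at SAUSA300_1933 (2.89, 130 UMIs against 542 reads, 117 of these UMIs in 3 barcodes) were higher, and SAUSA300_1495 was lower (-3.98, 3 UMIs against 1628 reads, counting interval -6.39 to -2.56). For 2.01, exponential sums correlated with exponential bulk at 0.887 and with stationary bulk at 0.713, and stationary sums at 0.526 and 0.770. The replicate correlations moved with the pseudocount, to 0.302 with 0.1 CPM and 0.766 with 10 CPM in E. coli.

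Libraries 2.01 and 2.01no_det compare preparations whose labels differ by no_det, which the labels do not spell out. The median depth in 2.01 over that in 2.01no_det was 1.49 for exponential E. coli (1.39 to 1.64), 1.21 for stationary E. coli (1.10 to 1.26, and 1.06 with an interval of 0.98 to 1.11 at a minimum of 40 UMIs) and 1.46 for S. aureus (1.32 to 1.64). Barcodes were 6.03, 5.80 and 6.06 times as many, and with minimums of 10 and 40 UMIs 3.99 and 12.9 times for stationary E. coli and 4.93 and 11.2 times for S. aureus. Few features differed beyond 2-fold in share with a prior count of 5, which shrinks ratios of low counts, with 42 higher and 2 lower in 2.01 of 979 in exponential cells, 18 and 1 of 469 in stationary cells and 4 and 1 of 288 in S. aureus. Higher in 2.01 in exponential cells were fhuE, the ferric coprogen receptor (116 UMIs against 1), ydeTSR (90 against 1) and murJ (356 against 10). In the stationary cells the colanic acid operon wza-wzb-wzc-wcaAB had 60 UMIs against 0. In 2.01, 90 of 119 UMIs of fhuE sat in reverse transcription well 30, 28 of 102 UMIs of ydeTSR in reverse transcription well 66 and 208 of 272 UMIs of the wza operon in round 2 well 22. Of 460 UMIs of murJ, 140, 116 and 107 sat in round 2 wells 12, 19 and 91. In 1.12det, exponential barcodes that the file names as with detergent had a median of 65 UMIs (61 to 68, n = 927 barcodes) and those without had 48 (45 to 52, n = 341). With a prior count of 5 no feature of 172 differed beyond 2-fold, although mlaFEDCB had 899 against 416 CPM (61 against 8 UMIs) without it. The lists had a median log2 ratio of 0.04 for ribosomal proteins and 0.08 for outer membrane proteins.

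Library 1.12 compared ligation oligos at 1x and 4x amounts in round 3. GFP-tagged barcodes, which were exponential cells, had a median of 66 UMIs at 1x (52 to 79, n = 114) and 153 at 4x (129 to 178, n = 79), a ratio of 2.32. RFP-tagged barcodes, stationary cells, numbered 9 at 1x and 82 at 4x, and 40 and 118 with a minimum of 10 UMIs. Over all barcodes the median was 42 at 1x (n = 177) and 29 at 4x (n = 403), a ratio of 0.69, while more barcodes, 2.28 times as many, passed the minimum. With a minimum of 10 or 40 UMIs the ratio of medians was 1.38 or 1.43 and that of barcodes 1.36 or 1.28, so the direction over all barcodes depended on the minimum.

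Single barcodes separated by growth stage. In 2.01, a cluster led by wrbA-yccJ, ykgMO, gadBC, osmC and hdeAB-yhiD held 3760 of 3762 stationary barcodes (99.9%), and clusters led by ybiT, ndk, bioP and rpsT or by cpxPQ held 3511 of 3512 exponential barcodes (99.97%). In 2.01no_det all 649 stationary and all 582 exponential barcodes fell into clusters of their own stage. Marker shares were 29.0% exponential and 0.0438% stationary markers in exponential cells, and 2.10% and 9.19% in stationary cells. With barcodes thinned to 20 UMIs, 84.2% of stationary barcodes and 0.968% of exponential barcodes held a stationary marker. Where the stage was not given by well, GFP-tagged barcodes fell into exponential-like clusters in 917 of 936 (98.0%) in 1.06, 2039 of 2083 (97.9%) in 1.10 and 193 of 193 in 1.12. RFP-tagged barcodes fell into stationary-like clusters, with yeaGH, gadAXW, adiY or phoA-psiF among their leading features, in 151 of 160 (94.4%), 458 of 599 (76.5%) and 91 of 91. Stationary markers took 0.677%, 0.924% and 2.53% of UMIs in RFP-tagged barcodes of 1.06, 1.10 and 1.12, below the 9.19% of stationary cells of 2.01. Exponential markers took 7.97%, 13.8% and 4.14%, above the 2.10% in those cells of 2.01. In 1.10, 116 RFP-tagged and 773 untagged barcodes lay in an unnamed cluster of 900 barcodes led by the methionine genes metF, metBL, mmuPM and metNIQ and by hcxA. The exponential cells of 1.12det formed 5 clusters with no stage name. Names rest on differences between clusters of a library, so in a library of a single stage a missing name does not tell the stage. Exponential markers took 28.0% of UMIs without and 28.4% with detergent in 1.12det, and stationary markers 0.0364% and 0.0501%, near the shares in exponential cells of 2.01. The 1.06 and 1.10 shares depended on the settings. With a minimum of 40 UMIs 0 of 624 GFP-tagged barcodes of 1.06 lay in a named exponential-like cluster, 485 in unnamed clusters and 139 (22.3%) in stationary-like clusters. With thinning 11.4% of RFP-tagged barcodes of 1.10 lay in a stationary-like cluster, 72.6% in unnamed clusters and 16.0% in exponential-like clusters.

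**Figure D5:**
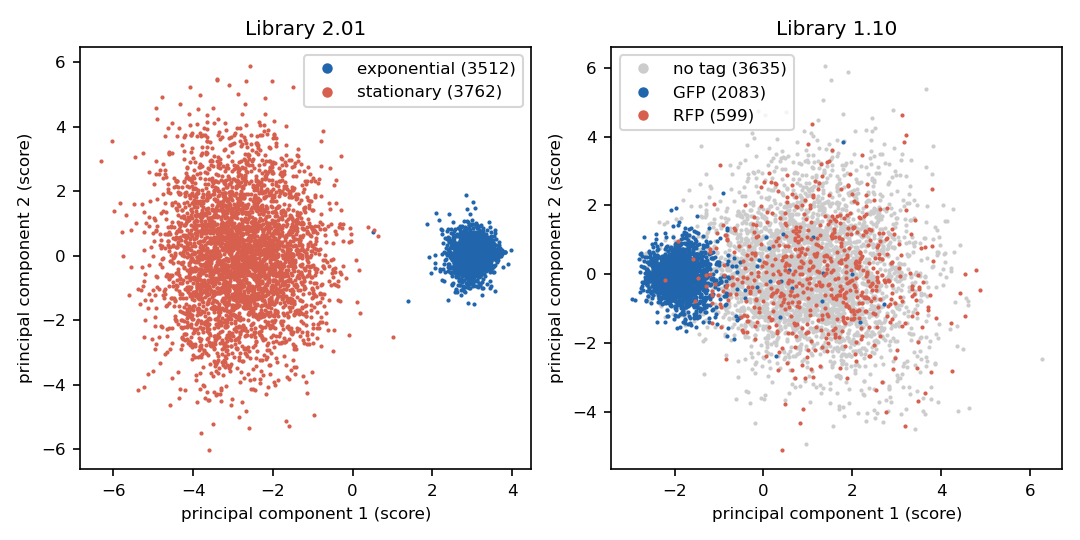
First and second principal component scores of E. coli barcodes in 2.01, coloured by the growth stage of their well, and in 1.10, coloured by reporter tag. Each point is a barcode; 3512 exponential and 3762 stationary barcodes of 2.01 lie apart along the first component.

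Much of the phiSA3 prophage RNA of 1.06SaEc was held by few S. aureus barcodes. In 1.06SaEc, 3 of 4255 barcodes (0.0705%, exact binomial 95% interval 0.0145 to 0.206%) had at least 5 UMIs of prophage phiSA3, and an even spread would give 0.00127 barcodes. In these barcodes phiSA3 took 118 of 135 UMIs (87.4%), 87 of 104 (83.7%) and 27 of 35 (77.1%), which made 56.4% of all 411 phiSA3 UMIs of the library. The leading features were operons at CP000255 2090666 to 2102092 (117 UMIs in these barcodes and 7 in all others), 2104288 to 2110116 (35 and 4) and 2112006 to 2116517 (19 and 6). No barcode passed in the replicate library (0 of 3213), 2.01 (0 of 1219) or 2.01no_det (0 of 201), which allows shares of up to 0.0934%, 0.246% and 1.49% by a floor of 3 counts and 0.115%, 0.302% and 1.82% by the exact interval. Prophage phiSA2 had no barcode with 5 UMIs in these 4 libraries.

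Few well-covered bulk transcripts of exponential GFP E. coli differed between fixed and unfixed cells. Of 1468 features with at least 100 reads in either library, with a prior count of 5, 2 were over 2-fold higher in fixed cells, ghrA (100 against 42 reads) and frwCB (log2 ratio 1.09), and 2 were over 2-fold lower, isrC-flu (-1.24, 50 against 127 reads) and the tRNA gene proK (-1.16). With a minimum of 20 reads 16 of 2202 were higher and 12 lower. Small and stable RNAs were lower as a group (median -0.27, 0 of 7 higher, percentile 0.04 among random lists), including the signal recognition RNA ffs (-0.89) and csrB (-0.73, 2635 against 4446 reads). Phosphate starvation had a median of -0.28 (1 of 4 higher, percentile 1.87), purine and pyrimidine synthesis -0.12 (1 of 17, percentile 1.83) and ribosomal proteins -0.04 (8 of 20, percentile 65.7). The correlation of fixed and unfixed profiles was 0.991 across features, and that of both fixed exponential libraries was 0.983.

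Preservation of unfixed exponential cells was compared by flash freezing, immediate RNAProtect and a 2 minute spin before RNAProtect, but the labels do not say which column of the table holds which. Of 1039 features 17 (1.64%) ranged over more than 2-fold among the 3 columns with a prior count of 5, led by cold shock genes, and with a minimum of 20 reads 65 of 1881 (3.46%) did. The cold shock list of 6 features took 4.37%, 4.26% and 5.27% of reads outside ribosomal RNA in the first to the third column. The CPM of cspH was 16.1, 14.4 and 114, that of cspG 251, 267 and 1569, that of cspB 168, 187 and 932, and that of cspF 27.0, 29.4 and 120. The tRNA operon glyVXY had 191, 300 and 493 CPM. Ribosomal proteins took 38.2%, 37.3% and 37.6% of reads outside ribosomal RNA, and small and stable RNAs 15.2%, 14.9% and 13.0%.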

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

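No test was run on the results in this part, which were picked by rules set in advance for differences between groups and for signals in data that the comparisons leave out.

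The PETRI-seq and the bulk stage tests called 13 features in opposite directions, and the difference between the assays was not tested. In stationary cells purHD (-4.79, SE 0.37, against 1.16, SE 0.24, as log2 fold changes in PETRI-seq and bulk), purC (-2.81 against 1.37), purT (-3.52 against 1.27) and purA (-0.82 against 1.06), all of purine synthesis, were lower in PETRI-seq and higher in bulk. The same held for metBL (-1.48 against 4.20), metK (-2.51 against 1.08), glyA (-1.75 against 1.93), tcyP (-1.58 against 3.20), dppABCDF (-0.95 against 1.78) and yobF-cspC (-0.82 against 1.01). The pyruvate transporter gene btsT (1.74 against -4.16), ydhR (3.47 against -1.01) and sdaA (0.85 against -0.99) were higher in PETRI-seq and lower in bulk.

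Antisense features, left out of the comparisons except for an alternative that kept them in the PETRI-seq stage test, held UMIs in all PETRI-seq libraries whose files list them. Their share of UMIs outside ribosomal RNA was lowest in the 1.06SaEc replicate at 9.43% and highest in 2.01 at 17.01%, with 9.84% in 1.06SaEc, 15.1% in 2.01no_det, 16.4% in 1.12 and 14.1% in 1.12det.

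The wild-type bulk table holds an exponential and a stationary library, and the labels do not say which column is which, so neither entered a test. RpoS and general stress features took 0.0352% of reads outside ribosomal RNA in its first column and 6.78% in its second.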

How the results depend on the processing

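Settings added after seeing the data were 1.12 by reporter tag, antisense features kept, ribosomal RNA counted in the mixing and thinned clusters. The cause of a change was not tested unless the setting itself gives it, as fewer UMIs or barcodes do. PETRI-seq stage calls went from 848 to 557 with DESeq2, 318 with sums thinned to the smallest (379 features tested) and 528 with 1.12 added (704 tested). Of the 848 calls, 549 remained with DESeq2, 307 of 330 tested remained with thinning and 525 of 551 with 1.12, and with library totals 734 remained and 3 were called the other way. With antisense features kept 1229 of 1693 were called (538 up, 691 down). Without the library block 867 were called (441 up, 426 down) and 844 of the 848 remained. With 1 library kept, 839 to 848 of the 848 had the same direction, as values since no residual degrees of freedom are left. For PETRI-seq features named in the text, 570 values under other settings kept direction and side of the threshold, and 9 kept direction only. Of the 1320 bulk calls, 1075 remained with DESeq2, 1162 with library totals, and 1320 kept direction with either exponential library left out. No paired analysis was possible because bulk labels pair no libraries, and a term for the table could not be fitted because all 3 stand in the same table. With library totals ompF in bulk was 0.048 in place of -0.33, and the other 159 values of bulk features kept direction and side.

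Camera called 10 PETRI-seq lists, against 0 with an estimated correlation and 0 with fry, and 10 bulk lists, against 0 and 5. With 1 residual degree of freedom in each fit, the estimated correlation could hardly call a list, so its 0 calls cannot decide. The 0 PETRI-seq calls of fry rest on the same 1 residual degree of freedom and cannot show that a list did not move. The 5 bulk lists of fry were RpoS, ribosome hibernation and acid resistance, which camera called, and the TCA cycle and glyoxylate use (adjusted p = 0.025 for both), which it did not. Fry also gave the other direction for the PETRI-seq SOS response (adjusted p = 0.901) and iron uptake (adjusted p = 0.238) and for bulk outer membrane proteins (adjusted p = 0.229).

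The share of mixed barcodes in 1.06SaEc was 1.07% with a purity of 95% and 1.37% with a minimum of 40 UMIs. In its replicate it was 1.23% with a purity of 95%, 0.639% with a minimum of 10 and 1.40% with 40. In 2.01 it was 0.393% and 17.3% with purities of 80% and 95%, 4.59% and 1.81% with minimums of 10 and 40, and 0.640% with ribosomal RNA counted. In 2.01no_det these were 0.136%, 7.47%, 2.43%, 0.272% and 0.204%. Median depth with minimums of 10 and 40 UMIs was 36.5 and 71 for 1.06SaEc E. coli, 18 and 47 for its S. aureus, 223 and 238.5 for 2.01 exponential E. coli, 29 and 50 for stationary E. coli and 46 and 65 for S. aureus. Depth ratios of 2.01 over 2.01no_det with these minimums were 1.45 and 1.06 for stationary E. coli and 1.70 and 1.25 for S. aureus. The ligation ratio over all barcodes was 1.38 and 1.43 in place of 0.69, and RFP-tagged barcodes gave no ratio at 40 UMIs.

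With pseudocounts of 0.1 and 10 CPM, at least 10 counts in both and all barcodes, the replicate correlation was 0.302, 0.766, 0.970 and 0.540 in E. coli and 0.705, 0.947, 0.980 and 0.928 in S. aureus. For 1.06SaEc against bulk it was 0.767, 0.885, 0.875 and 0.787 in E. coli and 0.873, 0.939, 0.894 and 0.935 in S. aureus. With a minimum of 20 reads, 28 features differed over 2-fold between fixed and unfixed bulk and 65 between preserved libraries.

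For clusters, k-means, a minimum of 40 UMIs, all features with at least 50 UMIs and thinning are given in this order. The shares of GFP-tagged barcodes in exponential-like clusters were 99.6%, 0%, 99.3% and 96.4% in 1.06. In 1.10 they were 99.2%, 99.0% and, with thinning, 88.0%. RFP-tagged barcodes lay in stationary-like clusters in 83.8%, 64.3%, 98.8% and 76.2% in 1.06 and 85.1%, 97.5%, 98.2% and 11.4% in 1.10. In 2.01 the exponential share was 100% with k-means and with 40 UMIs, and the stationary share 99.3% with thinning. In 2.01no_det the stationary share was 99.0% and in 1.12 the GFP share 94.4%, both with 40 UMIs. With at least 3 prophage UMIs, phiSA3 passed in 6 barcodes of 1.06SaEc, 1 of the replicate, 12 of 2.01 and 2 of 2.01no_det, and phiSA2 in 1 of 2.01. An even spread would give 0.882, 0.0534, 5.96 and 0.826 barcodes for phiSA3, in this order, and 0.251 for phiSA2 in 2.01.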

Other observations

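The tests of free phiSA3 RNA, of signals bound to a well's oligo and of other splits of the sums, as well as the gene sets, the deciding limits and the thinning of 2.01 for methionine and the thresholds for single wells, were chosen after the results were seen. The wild-type bulk columns, which the labels do not assign to a growth stage, differed across most E. coli lists. Ribosomal proteins took 41.6% of reads outside ribosomal RNA in the first column and 3.69% in the second, and translation factors 10.7% and 1.61%. Cold shock features took 3.46% and 0.478%, and purine and pyrimidine synthesis 1.55% and 0.429%. In the opposite direction, acid resistance took 0.00826% and 2.63%, phosphate starvation 0.0226% and 2.29%, anaerobic and fermentation features 0.251% and 2.47%, and small and stable RNAs 15.5% and 34.5%. Across features, log2 CPM of the exponential sums of 2.01 had Pearson correlations of 0.871 with the first and 0.527 with the second column, and the stationary sums 0.433 and 0.768, but no stage was taken from these values.

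In 1.10, the exponential-like cluster of 2392 barcodes was led by genes for siderophore receptors and enterobactin synthesis and transport, cirA (64 UMIs inside and 2 outside the cluster), fiu (33 and 1), entCEBAH (44 and 2) and fepDGC (23 and 1), together with yjaA (12 and 0). The stationary-like cluster of 2967 barcodes was led by adiY (14 and 0), yjjI (35 and 2), glsA-ybaT (95 and 7), yeaGH (122 and 15) and aidB (28 and 3). In 1.12 the stationary-like cluster of 370 barcodes was led by phoA-psiF (67 and 0), phoBR (49 and 0) and dps (43 and 0).

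In 1.06SaEc, 3 S. aureus barcodes were dominated by phiSA3. Other barcodes of the same wells held phiSA3 at 0.941 times the share in all other wells, which argues against a signal bound to a well. The barcodes held at least 8 phiSA3 features each, which argues against 1 transcript counted many times, and phiSA3 RNA spread evenly would give 0.00127 such barcodes. These values are consistent with prophage expression in rare cells, a hypothesis found on this library and not tested, since other libraries had no such barcode and the design names no biological group for these barcodes.

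Some E. coli features of 2.01 were concentrated in single wells, in 29 pairs of a feature and a well with 21 features of 1239 and 0.184% of UMIs. In round 2 well 49 the gcl operon had 267 of its 402 UMIs, and in round 2 well 22 the wza operon had 208 of 272, with 41 of 52 UMIs in the same well of 1.10 and 25 of 27 in that of 1.12det. Over other libraries, 62.2% of 98 pairs (61 pairs) were over 5 times the well's share of UMIs, among them 19 of 28 in 1.10 and 17 of 25 in 2.01no_det but 1 of 6 in 1.06, 2 of 5 in 1.06SaEc and 1 of 4 in its replicate, so a signal bound to the barcode oligo of the well may be the source. The largest barcode held a median of 10% of the feature's UMIs in its well, which argues against few barcodes with many UMIs. No biological explanation was tested.

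In 1.10, 491 of 4234 barcodes with the RFP tag or none held UMIs of both methionine gene sets, one of metA, metB, metC, metE, metR and metH and the other of metN, metF, metK, mmuP and metJ, against 347 by chance (ratio 1.41, 1.33 to 1.49), an excess that restates the cluster of this library from which the sets were chosen. The ratio was 1.38 (1.22 to 1.55) with barcodes thinned to 20 UMIs and 1.38 (1.30 to 1.44) against draws within reverse transcription wells, both above the 1.2 under which depth or wells were to count as the cause, which argues against either as the whole cause in 1.10, while an upper limit of 1.5, set at first, lay above the uncorrected ratio and could not decide. With the RFP tag alone the ratio was 1.43 (1.29 to 1.58), but the labels of 1.10 give no growth stage for a tag, so mixed growth stages cannot be told apart from methionine genes that vary between cells of a stage, which was not tested. In 2.01, uncorrected for depth, the ratio was 1.67 in stationary (exact hypergeometric p = 8.8e-05) and 1.33 in exponential barcodes (p = 0.0037), but with thinning 9 stationary barcodes held both sets against 9.58 by chance (ratio 0.94) and 0 exponential barcodes against 0.556, so 2.01 shows no excess beyond depth at these counts. In 2.01no_det the uncorrected ratio was 1.41 (5 barcodes, exact p = 0.27) in stationary and 1.04 (4 barcodes, exact p = 0.55) in exponential barcodes.

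With 1.12 added, the 6 sums gave 520 calls in a fit without the library block, and this was 1 of the 10 splits of the sums, the highest of the others giving 0. A total of 10 splits cannot give a share under 0.05.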
